A study of Homo sapiens with 8 samples.

How the data were processed

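The series holds RNA sequencing of 2 human hepatocellular carcinoma cell lines, PLC/PRF/5 and SNU449. Cells of each line carried either shPLKO, the control vector, or shPSPH, a short hairpin RNA against PSPH. PSPH encodes phosphoserine phosphatase, the enzyme of the last step of serine synthesis from a glycolysis intermediate. Per the labels' protocols, all cultures were treated with TNF-a for 24 h, RNA was extracted with TRIzol, and libraries were made from poly-A selected mRNA. There were 4 groups of 2 libraries, 8 libraries in all, and no untreated sample, so the response to TNF-a itself has no comparison here. The labels do not say whether the 2 libraries of a group came from separate cultures, so p values measure only the spread between these libraries. The column headers of the knockdown libraries carry the number 1 after PSPH in PLC/PRF/5 and the number 2 in SNU449. The labels do not say whether these numbers stand for different hairpins, so a difference between lines can also be a difference between hairpins.

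The deposited files give FPKM, fragments per kilobase of gene scaled to the library total, for 19225 gene rows per library, as computed by the authors. The submitters' processing notes name TopHat, an aligner, and HTSeq, a read counter, without versions or settings. They state no genome build, annotation or gene lengths. Of the rows, 1130 were at 0 in all libraries. Symbols of 27 rows had been turned into dates by spreadsheet software, and 4 rows shared a symbol. In 23 rows the symbol sorted before that of the row above. PSPH also stood out of alphabetical order. The row of PSPH stood at place 3958, whereas CCL8 stood at place 13191, between PSPC1 and PSPN. Nothing in the files explains this order, and values were used as deposited.

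FPKM is a read number divided by a gene length and a library total, so within a gene all values should lie on whole reads at a common length. Library totals and lengths that place the values on whole reads were searched with Python 3.11.15 and numpy 2.4.6, over lengths from 100 to 130000 bases, with a tolerance of 0.003 reads. The totals found were 80307189 and 86747947 reads for PLC/PRF/5 shPLKO, 86346770 and 93892559 for PLC/PRF/5 shPSPH, 86587822 and 63332267 for SNU449 shPLKO, and 84154834 and 87231105 for SNU449 shPSPH. Of the 16468 rows above 0 in at least 4 libraries, 16427 (99.75%) lay on whole reads in every library. The other 41 rows did not. A rule against lengths that are multiples of the true one was added after the first outcome of this search had been seen. On simulated data the search found 30 of 30 altered rows, called 0 unaltered rows, and recovered 8 of 8 library totals. The 41 genes stayed in the tests, are marked where named ("values not whole reads"), and were left out in an alternative fit.

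The design written before the data were examined foresaw a count test on whole counts, with limma-trend for the case that the files held normalized values. As they hold FPKM, genes were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend) on log2(FPKM + 1), without further scaling. The fit took all 8 libraries with 4 group means, which left 4 residual degrees of freedom, to which the prior added 6.5. Genes at FPKM of at least 1 in at least 2 libraries entered, 12344 in number. This filter was set once the unit was known. Contrasts were shPSPH against shPLKO in each line, the difference of these effects (PLC/PRF/5 minus SNU449), and PLC/PRF/5 against SNU449 among the controls. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale are smaller than ratios of FPKM for genes at low level. With 2 libraries against 2, a two-sided permutation test of a gene alone cannot go below p = 0.33, so calls rest on the spread pooled over groups and genes. Data were also simulated for these groups, with a coefficient of variation of 5% beyond read sampling for every gene in every group. In them the fit found 63 of 64 genes changed 1.5-fold, 66 of 66 changed 2-fold and 65 of 65 changed 4-fold. It called 15 of 11603 unchanged genes, 7.2% of all calls. The measured groups differed in spread and had a far larger share of called genes, so the simulation does not give the share of false calls in them.

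Before the data were examined, 26 gene lists and 4 sets of markers of other cell types were fixed. The list of mitochondrially encoded transcripts had no member in the files, which left 25. Lists of at least 5 tested members were tested with limma's camera, which asks whether the members changed more in one direction than the other tested genes, with a preset correlation between genes of 0.01, two-sided, Benjamini-Hochberg adjusted over the lists. Camera with an estimated correlation and fry were run beside it. In fry, one p value tests whether the genes of a list move, on balance, in the same direction, and a mixed p value whether they change in either direction, and neither compares a list with other genes. On simulated data camera found 1 of 1 shifted list and called 0 of the 24 others. Genes varied independently in these data, so they cannot show how camera with the preset correlation behaves where members vary together. Genes called in both lines were compared with Fisher's exact test, one-sided.

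The genes named in the text follow a rule written before the data were examined. It takes PSPH, PHGDH, PSAT1, SHMT1 and SHMT2, the 10 largest rises and the 10 largest falls per line, and up to 4 members of each list. It further takes 6 genes called in both lines in the same direction and 6 in opposite directions, the 6 smallest adjusted p values for a difference between lines, and 5 genes higher in each control line. Of the list members, the text prints the first 2 of each changed list, a limit set after the list results had been seen. The rule's level minimum, written for read counts scaled to depth, was applied to FPKM, at 5. XIST and Y-linked genes were passed over, and some genes the rule names are not reported here. Positions were taken from GENCODE 29.

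Alternatives were another scaling, other pseudocounts, other filters on low values, limma-voom on the recovered reads, fits of each line alone, the replicate number as a block, a minimum fold change, each library left out, and the genes not on whole reads left out. Pseudocounts and the last of these were added after the data had been seen. Deviations of the replicates with the same number were nearly uncorrelated (r = 0.02 in PLC/PRF/5 and 0.17 in SNU449, against -0.16 between the control lines, across genes), so numbers were not used as pairs. Figures were drawn with matplotlib 3.10.9, and pandas 2.3.3 read the tables.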

Results

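The messenger RNA of PLC/PRF/5 and SNU449 cells, established lines from human hepatocellular carcinoma, was compared between knockdown of PSPH and the shPLKO control. Both lines had been treated with TNF-a, an inflammatory cytokine, for 24 h. Each of the 4 groups had 2 libraries, of 63332267 to 93892559 reads as recovered from the values. Levels are mean FPKM ± SD (n = 2 libraries), and log2 fold changes of FPKM + 1 carry their SE. Replicates of a group correlated at r = 0.9985 to 0.9994 across genes, and the median coefficient of variation of a gene was 2.5% and 5.1% in PLC/PRF/5 (control and knockdown) and 5.3% and 2.5% in SNU449. The first principal component separated the lines with 92.4% of the variance. The second separated the PLC/PRF/5 groups (5.08%) and the third the SNU449 groups (1.78%).

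The first question was how far the hairpin lowered its target. PSPH fell from 34 ± 1.61 to 2.98 ± 0.513 FPKM in PLC/PRF/5, 11.4-fold lower (log2 fold change -3.14 ± 0.10, adjusted p = 5.2e-09). In SNU449 it fell from 20 ± 2.65 to 2.22 ± 0.162 FPKM, 9-fold lower (-2.70 ± 0.10, adjusted p = 9.6e-08). The level left was 8.8% and 11.1% of the control. The enzymes of the preceding steps of serine synthesis differed between the lines. PHGDH, the dehydrogenase of the first step, was at 14.5 ± 0.0451 and 14.1 ± 1.26 FPKM in PLC/PRF/5 control and knockdown (adjusted p = 0.63) and fell from 35.6 ± 1.25 to 22.4 ± 0.261 FPKM in SNU449 (-0.64 ± 0.063, adjusted p = 3.5e-05). PSAT1, the aminotransferase between them, was at 50.4 ± 1.70 and 49.8 ± 0.856 FPKM in PLC/PRF/5 (adjusted p = 0.83) and fell from 92.2 ± 6.59 to 70.5 ± 1.03 FPKM in SNU449 (-0.38 ± 0.057, adjusted p = 5.6e-04). The test of the difference between lines passed for both (adjusted p = 2.1e-04 for PHGDH and 0.0031 for PSAT1). The hydroxymethyltransferases that convert serine to glycine fell in both lines. SHMT1 fell by 0.76 and 0.52 and SHMT2 by 0.78 and 0.65 on the log2 scale in PLC/PRF/5 and SNU449 (adjusted p = 1.9e-06, 1.3e-04, 1.1e-06 and 2.0e-05). In GENCODE 29 on GRCh38, PSPH lies on the minus strand of chromosome 7, from 56011051 to 56051604, whereas the files give no coordinates. Reads of PSPH can be shared with the pseudogene PSPHP1, which the files do not resolve.

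**Figure D1:**
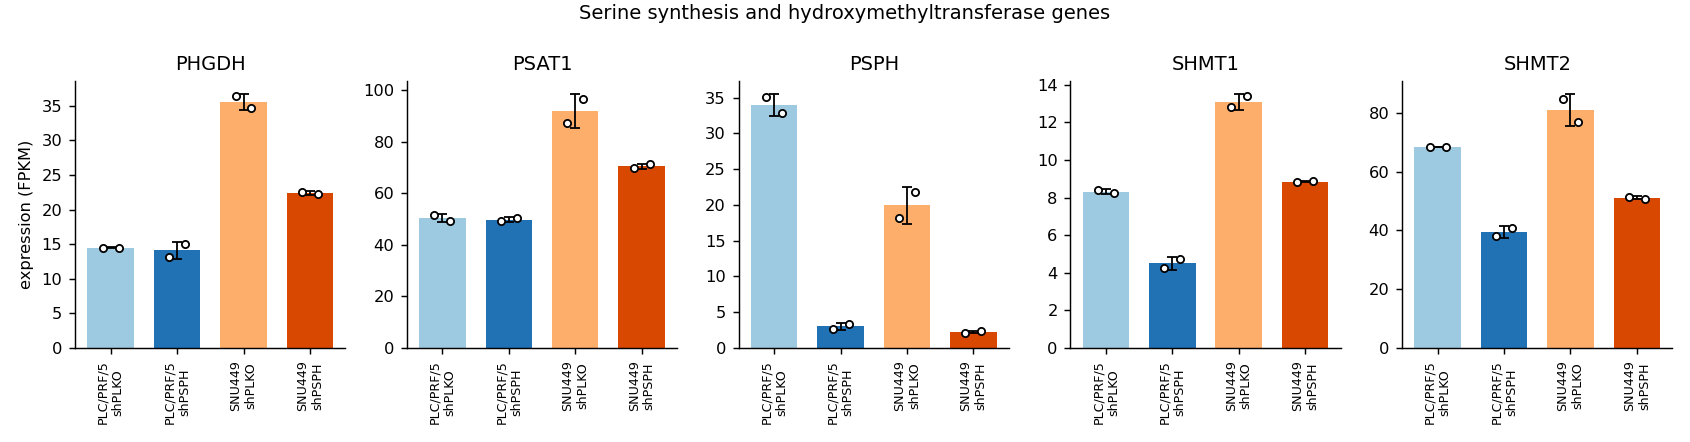
Expression in FPKM (vertical axes, from 0) of PHGDH, PSAT1, PSPH, SHMT1 and SHMT2 in the 4 groups, with bars for the mean, whiskers for the SD and circles for the 2 libraries. PSPH was at 34 and 20 FPKM in the controls of PLC/PRF/5 and SNU449 and at 2.98 and 2.22 FPKM after knockdown.

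The next question was which genes changed with the knockdown in PLC/PRF/5. CD9, a tetraspanin of the cell surface, rose from 3.52 ± 0.396 to 24.2 ± 2.10 FPKM (2.48 ± 0.073), and LAMB3, a laminin chain, from 2.86 ± 0.15 to 19.6 ± 0.00953 FPKM (2.41 ± 0.065). TTC17 rose from 23.7 ± 0.285 to 125 ± 3.67 FPKM (2.35 ± 0.050). MATN3, a matrilin of the extracellular matrix, rose 5.83-fold, EEF1A2, a translation elongation factor, 5.86-fold, and ACHE, acetylcholinesterase, 6.48-fold. The peptide hormone genes CCK (cholecystokinin), GAL (galanin) and CGB8 (a chorionic gonadotropin subunit) rose by 2.31, 2.11 and 2.05 on the log2 scale, and the protease gene CTSE (cathepsin E) by 2.25. Of these, CCK, CTSE and CGB8 were under 1 FPKM in the control. The adjusted p of these 10 genes lay between 8.0e-10 and 9.4e-08.

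Besides PSPH, the largest falls in PLC/PRF/5 included a gene of serine breakdown. SDS, serine dehydratase, fell from 7.53 ± 0.571 to 0.339 ± 0.0201 FPKM (-2.67 ± 0.075). CP, the copper carrier ceruloplasmin, fell from 44.9 ± 0.484 to 6.53 ± 0.280 FPKM (-2.61 ± 0.050), and CRH, corticotropin-releasing hormone, from 1104 ± 13.5 to 197 ± 12 FPKM (-2.48 ± 0.056). IGFBP1, which binds insulin-like growth factors, was 5.84-fold lower, LRP2, the endocytic receptor megalin, 8.03-fold, MMGT1 6.27-fold, CDK6, a kinase of the early cell cycle, 5.13-fold, and TGM2, a transglutaminase, 4.46-fold. The adjusted p of these 8 genes lay between 6.0e-10 and 1.7e-08.

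Among the fixed lists, genes of DNA replication and of glutathione and oxidant defence fell in PLC/PRF/5. Of 38 genes of G1/S and DNA replication, 36 fell and 1 rose (37 changed when adjusted over the list alone), with a median log2 fold change of -0.56 (adjusted p = 6.7e-11, and adjusted p = 0.072 with an estimated correlation). Examples were GINS2 and MCM4, parts of the replicative helicase, which fell by 1.08 ± 0.057 and 0.92 ± 0.051. Of 36 genes of G2/M and mitosis, 22 fell and 3 rose (25 adjusted over the list alone), with a median of -0.16 (adjusted p = 0.0018, and adjusted p = 0.45 with an estimated correlation). MKI67, a proliferation marker, fell by 1.18 ± 0.10, and AURKA, a mitotic kinase, by 0.56 ± 0.052. Of 27 genes of NRF2 and glutathione, 21 fell and 1 rose (22 adjusted over the list alone), with a median of -0.46 (adjusted p = 7.5e-06, and adjusted p = 0.27 with an estimated correlation). ABCC2, a conjugate export pump, fell by 0.93 ± 0.053, whereas the gene that rose was HMOX1, haem oxygenase (1.04 ± 0.053). Of 16 genes of the methionine cycle and methyl transfer, 11 fell and 2 rose (13 adjusted over the list alone), with a median of -0.29 (adjusted p = 0.024, and adjusted p = 0.27 with an estimated correlation). NNMT, nicotinamide methyltransferase, fell by 1.5 ± 0.077, and BHMT2, a homocysteine methyltransferase, by 0.98 ± 0.061. Of 10 acute phase genes, 8 fell and 1 rose (9 adjusted over the list alone), with a median of -0.58 (adjusted p = 0.0085, and adjusted p = 0.34 with an estimated correlation). CP was the largest fall, and SERPINA3, a protease inhibitor, was the gene that rose (0.91 ± 0.059).

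Genes of antigen presentation and histones rose in PLC/PRF/5. Of 19 genes of MHC class I presentation, 17 rose and 0 fell (17 adjusted over the list alone), with a median of 0.52 (adjusted p = 1.4e-06, and adjusted p = 0.27 with an estimated correlation). The list held 4 genes with values not whole reads, and without them its adjusted p was 5.9e-05. HLA-B (values not whole reads), a heavy chain of the complex, rose from 18.1 ± 0.890 to 74.8 ± 7.99 FPKM (1.99 ± 0.072), and TAP1, the peptide transporter, from 51.2 ± 0.677 to 126 ± 3.78 FPKM (1.29 ± 0.047). All 9 replication-dependent histone genes rose (9 adjusted over the list alone), with a median of 1.35 (adjusted p = 4.1e-05, and adjusted p = 0.12 with an estimated correlation). HIST1H2BK rose from 42.0 ± 1.24 to 103 ± 7.24 FPKM and HIST1H2BD from 3.54 ± 0.0761 to 12.7 ± 1.07 FPKM. Most transcripts of this class lack a poly-A tail, so poly-A selected libraries hold a small part of them. Of 30 genes of autophagy and lysosome, 21 rose and 2 fell (23 adjusted over the list alone), with a median of 0.26 (adjusted p = 6.3e-04, and adjusted p = 0.27 with an estimated correlation). ULK1, a kinase that starts autophagy, rose by 0.94 ± 0.051 and CTSL, a lysosomal protease, by 0.83 ± 0.058. Of 31 mesenchymal and matrix genes, 15 rose and 4 fell (19 adjusted over the list alone), with a median of 0.08 (adjusted p = 0.017, and adjusted p = 0.47 with an estimated correlation). VIM, vimentin, rose 2.99-fold. Of 30 genes of the ATF4 amino acid response, 17 rose and 6 fell (24 adjusted over the list alone), with a median of 0.19 (adjusted p = 0.021, and adjusted p = 0.45 with an estimated correlation). SLC3A2, a subunit of amino acid transporters, rose from 70.2 ± 1.70 to 293 ± 27.1 FPKM, whereas ATF5, a transcription factor, fell by 0.99 ± 0.052. The call of the ATF4 list was lost without replicate 2 of the PLC/PRF/5 knockdown, at a median of 0.18.

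In all, 7729 of 12344 tested genes (62.6%) changed in PLC/PRF/5, 3830 up and 3899 down (limma, adjusted p under 0.05). Of these, 443 changed by at least 1 on the log2 scale, 201 up and 242 down, and the median change of a called gene was 0.38 on that scale. Of 25 lists, 10 changed, 5 in each direction, and 0 were called with an estimated correlation. Fry called 20 lists in their own direction and 25 in its mixed form.

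The list of NF-kB feedback and TNF targets had 19 genes that rose and 7 that fell in PLC/PRF/5, with an adjusted p of 0.056 for the list. For p53 targets, 13 rose and 6 fell (adjusted p = 0.071), and for interferon-stimulated genes 16 rose and 7 fell (adjusted p = 0.32). The serine and glycine list had 2 rises and 6 falls (adjusted p = 0.34), folate-dependent metabolism 5 and 9 (0.24), immune checkpoint genes 5 and 1 (0.28), and fatty acid synthesis 2 and 7 (0.28). Oxidative phosphorylation had 9 rises and 5 falls (0.34), chemokines and cytokines 9 and 12 (0.46), hepatocyte genes 8 and 12 (0.46), and epithelial genes 3 and 6 (0.65). The unfolded protein response had 6 and 6 (0.80), glycolysis and hypoxia 12 and 11 (0.80), cholesterol synthesis 8 and 7 (0.94), and cytosolic ribosomal proteins 5 and 6 (0.94). For the chemokine, hepatocyte and epithelial lists the median was above 0 (0.02, 0.05 and 0.03), whereas the mean and the direction of the test were negative.

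The same comparison was made in SNU449. UBD, a ubiquitin-like modifier, rose from 2.01 ± 0.242 to 23.9 ± 0.847 FPKM (3.05 ± 0.066), and CCL5, a chemokine, from 6.37 ± 0.232 to 51.4 ± 2.47 FPKM (2.83 ± 0.061). RND1, a small GTPase, rose 5-fold, and KCNK6, a potassium channel, 3.47-fold. IGFBP1 rose from 49.7 ± 0.427 to 152 ± 3.34 FPKM (1.59 ± 0.066), FN1, fibronectin, from 37.3 ± 5.32 to 99.8 ± 2.20 FPKM (1.40 ± 0.095), and CX3CL1, a membrane-bound chemokine, from 2.58 ± 0.0151 to 7.83 ± 0.3 FPKM (1.30 ± 0.061). PPP1R14A, an inhibitor of myosin phosphatase, rose by 1.43 and SLFN5 by 1.40 on the log2 scale. The adjusted p of these 9 genes lay between 1.2e-09 and 2.3e-05.

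Besides PSPH, PSG1 and PSG5, pregnancy-specific glycoproteins, fell in SNU449 from 13.7 ± 0.860 to 2.66 ± 0.00177 FPKM and from 25 ± 0.413 to 9.12 ± 0.426 FPKM. METAP2, a methionine aminopeptidase, fell from 30.7 ± 2.37 to 7.55 ± 0.0224 FPKM (-1.89 ± 0.063), and SDHD, a subunit of succinate dehydrogenase, from 34.5 ± 2.40 to 10.2 ± 0.506 FPKM (-1.67 ± 0.063). HSDL2, of the hydroxysteroid dehydrogenase-like proteins, was 3.06-fold lower, IGFBP2 2.96-fold, PI4K2B, a phosphatidylinositol kinase, 2.74-fold, and TMEM9B 2.69-fold. RPL14, a ribosomal protein gene, fell from 550 ± 32.2 to 231 ± 4.95 FPKM (-1.24 ± 0.062). The adjusted p of these 9 genes lay between 3.6e-08 and 1.5e-05.

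Lists of proliferation and of ribosomal proteins fell in SNU449. Of the genes of G1/S and DNA replication, 35 of 38 fell and 0 rose (36 adjusted over the list alone), with a median of -0.36 (adjusted p = 3.1e-14, and adjusted p = 0.043 with an estimated correlation). MCM3 and MCM10, of the replication machinery, fell by 0.54 ± 0.052 and 0.57 ± 0.056. Of the genes of G2/M and mitosis, 33 of 36 fell and 0 rose (34 adjusted over the list alone), with a median of -0.37 (adjusted p = 3.8e-13, and adjusted p = 0.19 with an estimated correlation). KIF20A, a mitotic kinesin, fell by 0.72 ± 0.051 and NUSAP1, a spindle protein, by 0.80 ± 0.059. Of 35 cytosolic ribosomal protein genes, 29 fell and 0 rose (31 adjusted over the list alone), with a median of -0.27 (adjusted p = 8.3e-10, and adjusted p = 0.32 with an estimated correlation). RPL14 had the smallest adjusted p among them.

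Metabolic lists fell in SNU449 by smaller amounts. Random lists matched to the ribosomal protein genes on gene length, GC content and level, described below, had a median of -0.14 in this line. The metabolic lists were not matched in this way, so whether such a trend contributes to their medians was not tested. In oxidative phosphorylation 7 of 31 genes fell and 0 rose (4 adjusted over the list alone), with a median of -0.11 (adjusted p = 0.0092, and adjusted p = 0.55 with an estimated correlation), SDHD being the largest fall and NDUFA9, of complex I, falling by 0.31 ± 0.051. In fatty acid synthesis 7 of 17 fell and 0 rose (7 adjusted over the list alone), with a median of -0.14 (adjusted p = 0.010, and adjusted p = 0.19 with an estimated correlation). The desaturases SCD and FADS1 fell by 0.70 ± 0.054 and 0.35 ± 0.052. In glycolysis and hypoxia 11 of 28 fell and 3 rose (17 adjusted over the list alone), with a median of -0.17 (adjusted p = 0.015, and adjusted p = 0.26 with an estimated correlation). The glycolytic enzymes PGK1 and PGAM1 fell by 0.60 ± 0.052 and 0.49 ± 0.048. The glycolysis call was lost without replicate 1 of the SNU449 control, at a median of -0.13. In folate-dependent metabolism 8 of 16 fell and 1 rose (9 adjusted over the list alone), with a median of -0.15 (adjusted p = 0.017, and adjusted p = 0.19 with an estimated correlation). TYMS, thymidylate synthase, fell by 0.46 ± 0.055 and SLC25A32, a mitochondrial folate carrier, by 0.59 ± 0.075. In serine and glycine synthesis and uptake, a list without PSPH, 6 of 18 fell and 2 rose (8 adjusted over the list alone), with a median of -0.10 (adjusted p = 0.042, and adjusted p = 0.19 with an estimated correlation), SHMT2 and PHGDH being the smallest adjusted p values. The serine list's call was lost without replicate 2 of the SNU449 control, at a median of -0.09, and without either PLC/PRF/5 knockdown library, at a median of -0.10. It was also lost in a fit of the 4 SNU449 libraries alone, and with a pseudocount of 0.1.

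Lists of immune and matrix genes rose in SNU449. In MHC class I presentation 12 of 19 genes rose and 1 fell (14 adjusted over the list alone), with a median of 0.39 (adjusted p = 3.0e-06, and adjusted p = 0.19 with an estimated correlation). Without its 4 genes with values not whole reads, the adjusted p was 1.5e-04. HLA-B (values not whole reads) rose from 57.5 ± 2.96 to 116 ± 2.47 FPKM. In mesenchymal and matrix genes 17 of 31 rose and 4 fell (21 adjusted over the list alone), with a median of 0.19 (adjusted p = 3.0e-06, and adjusted p = 0.19 with an estimated correlation). COL5A1, a collagen chain, rose 2.44-fold and MMP9, a matrix metalloproteinase, 2.57-fold. In interferon-stimulated genes 20 of 32 rose and 3 fell (24 adjusted over the list alone), with a median of 0.24 (adjusted p = 8.9e-05, and adjusted p = 0.10 with an estimated correlation). IFIT2, an antiviral protein, rose from 3.96 ± 0.0158 to 9.70 ± 0.253 FPKM. In NF-kB feedback and TNF targets 15 of 32 rose and 1 fell (17 adjusted over the list alone), with a median of 0.13 (adjusted p = 0.0013, and adjusted p = 0.19 with an estimated correlation). TRAF1, a signalling adaptor of TNF receptors, rose by 0.85 ± 0.065, and IRF1 (values not whole reads), a transcription factor, by 0.61 ± 0.056.

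Further lists rose in SNU449. In autophagy and lysosome 15 of 30 genes rose and 3 fell (20 adjusted over the list alone), with a median of 0.15 (adjusted p = 0.0044, and adjusted p = 0.19 with an estimated correlation). GABARAPL1, of autophagosomes, rose by 0.66 ± 0.048 and CTSD, a lysosomal protease, by 0.67 ± 0.060. In acute phase genes 5 of 10 rose and 1 fell (6 adjusted over the list alone), with a median of 0.26 (adjusted p = 0.0090, and adjusted p = 0.20 with an estimated correlation). The complement genes CFB and C1S rose by 1.02 ± 0.060 and 1.10 ± 0.069. In hepatocyte genes 8 of 29 rose and 1 fell (9 adjusted over the list alone), with a median of 0.06 (adjusted p = 0.014, and adjusted p = 0.25 with an estimated correlation). Among them FOXA1, a liver transcription factor, rose by 0.60 ± 0.057. In the controls 27 of the 29 hepatocyte genes were higher in PLC/PRF/5. Some members, such as APOB and VTN, were under 1 FPKM in both SNU449 groups, where log2(FPKM + 1) leaves little room for a fall. In epithelial genes 7 of 13 rose and 1 fell (8 adjusted over the list alone), with a median of 0.17 (adjusted p = 0.015, and adjusted p = 0.19 with an estimated correlation). ELF3, an epithelial transcription factor, rose by 0.40 ± 0.053 and CLDN1, a tight junction protein, by 0.35 ± 0.047. Of 9 histone genes 5 rose and 0 fell (6 adjusted over the list alone), with a median of 0.34 (adjusted p = 0.032, and adjusted p = 0.19 with an estimated correlation). HIST1H2BD and HIST2H2BE rose by 0.44 ± 0.076 and 0.52 ± 0.092. Without a filter on low values, the calls of the epithelial and histone lists were lost, at medians of 0.01 and -0.04.

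In all, 4839 genes (39.2%) changed in SNU449, 2370 up and 2469 down, of which 68 changed by at least 1 on the log2 scale, 43 up and 25 down. The count was 2831 without replicate 1 of the SNU449 knockdown and 2848 without its replicate 2. With another scaling the share of rises among the called genes went from 49% to 55.8%. Of 25 lists, 17 changed, 9 up and 8 down, and 1, G1/S and DNA replication, was called with an estimated correlation. Fry called 21 lists in their own direction and 25 in its mixed form. The lists that did not pass camera were cholesterol synthesis (3 rises and 9 falls, adjusted p = 0.20), the unfolded protein response (6 and 2, 0.36), p53 targets (9 and 8, 0.36), the methionine cycle (4 and 6, 0.51), immune checkpoint genes (4 and 3, 0.51), the ATF4 response (9 and 9, 0.58), NRF2 and glutathione (8 and 7, 0.81), and chemokines and cytokines (5 and 8, 0.85). Mean and median differed in sign for the chemokine list (0.07 and -0.07) and the NRF2 list (0.01 and -0.03).

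**Figure D2:**
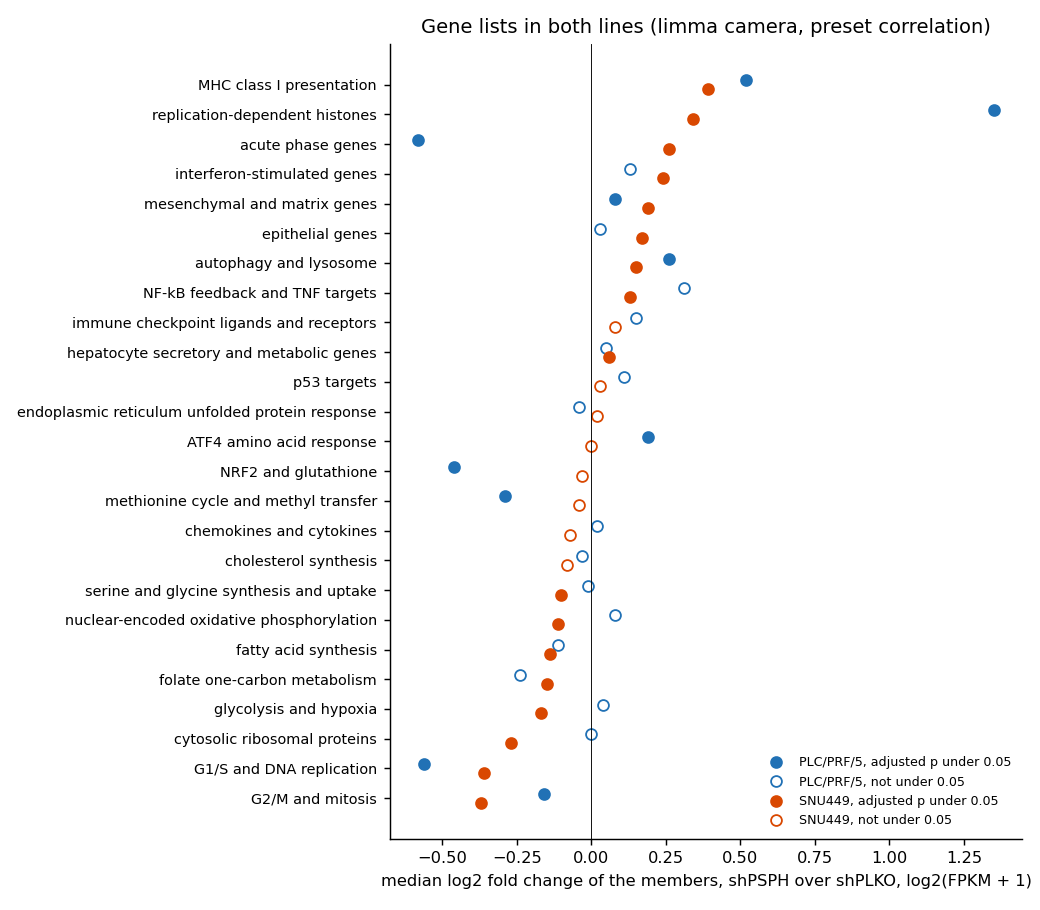
Median log2 fold change of FPKM + 1 after PSPH knockdown (horizontal axis) of the members of 25 gene lists (vertical axis) in PLC/PRF/5 (blue) and SNU449 (orange), filled where camera gave an adjusted p under 0.05. The list of G1/S and DNA replication stood at -0.56 and -0.36 and that of MHC class I presentation at 0.52 and 0.39.

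The next question was whether the lines shared a response. A small set of genes changed by at least 1 on the log2 scale in both. Besides PSPH, IGFBP3 fell in both lines, from 11.1 ± 0.343 to 2.65 ± 0.00150 FPKM in PLC/PRF/5 and from 184 ± 5.22 to 83.0 ± 0.411 FPKM in SNU449. KCNK6 rose by 1.33 and 1.5, RND1 by 1.15 and 1.70, and CCL5 by 1.22 and 2.83 on the log2 scale. CXCL10 (values not whole reads), a chemokine induced by interferon, rose by 1.45 and 1.33, from under 1 FPKM in the PLC/PRF/5 control. Chemokines did not rise as a class: of their list, 9 rose and 12 fell in PLC/PRF/5, and 5 rose and 8 fell in SNU449. CCL2 (values not whole reads), named outside the rule, was lower in both lines. Its libraries went from 106 and 96.7 to 36.1 and 27.8 FPKM in PLC/PRF/5, and from 52.7 and 57.1 to 25.6 and 27.3 FPKM in SNU449. Other genes changed in opposite directions. IGFBP1 fell in PLC/PRF/5 and rose in SNU449, as did TGM2 (-2.10 and 0.87), C1S (-0.94 and 1.10), IGFBP4 (-1.21 and 0.86) and KYNU, kynureninase of tryptophan breakdown (-1.14 and 0.87). SERPINA3 rose by 0.91 in PLC/PRF/5 and fell by 0.82 in SNU449.

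Of 3118 genes called in both lines, 1718 (55.1%) changed in the same direction and 1400 in opposite directions. The overlap was 815 genes for rises, against 735 expected from independent lists (one-sided Fisher's exact test, p = 5.1e-05), and 903 for falls, against 780 (p = 2.0e-09). For opposite directions the overlaps were 691, against 766 expected, and 709, against 749 (Fisher's exact test, p = 1 and 0.98). Fisher's test treats genes as independent, and both lines were called from 1 fit with a common spread per gene. Its p values therefore do not measure the strength of a shared response. Across all tested genes, which are not independent replicates, the fold changes of the lines correlated at Pearson r = 0.08 and a Spearman coefficient of 0.05. Across the 3118 genes called in both lines, Pearson r was 0.16. Of the 17 genes past 1 on the log2 scale in both lines, 16 went in the same direction, with PSPH, the target of the knockdown, among the 16. The count of genes called in both was 1766 without replicate 1 of the SNU449 knockdown and 1752 without its replicate 2. Among the lists, 6 changed in the same direction in both lines and 1, the acute phase genes, in opposite directions. With an estimated correlation, 0 lists were called in PLC/PRF/5 and 1 in SNU449, so 0 were called in both.

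**Figure D3:**
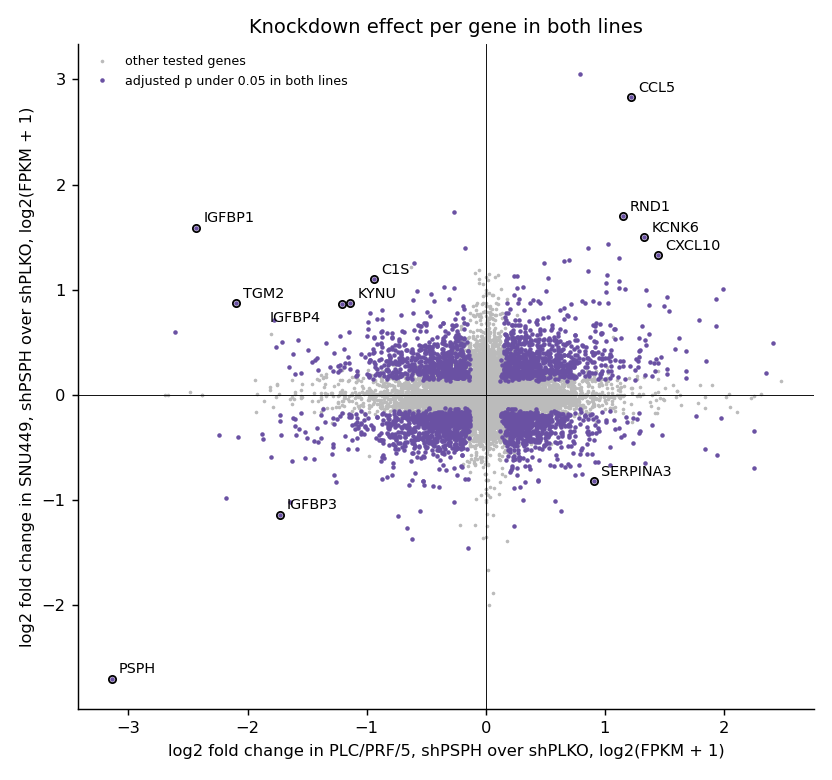
Log2 fold change of FPKM + 1 after PSPH knockdown in PLC/PRF/5 (horizontal axis) and SNU449 (vertical axis), with a point per tested gene, purple where called in both lines, and circles around named genes, of which CXCL10 has values not whole reads. PSPH stood at -3.14 and -2.70 and IGFBP1 at -2.43 and 1.59, and r was 0.08 across genes.

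**Figure D4:**
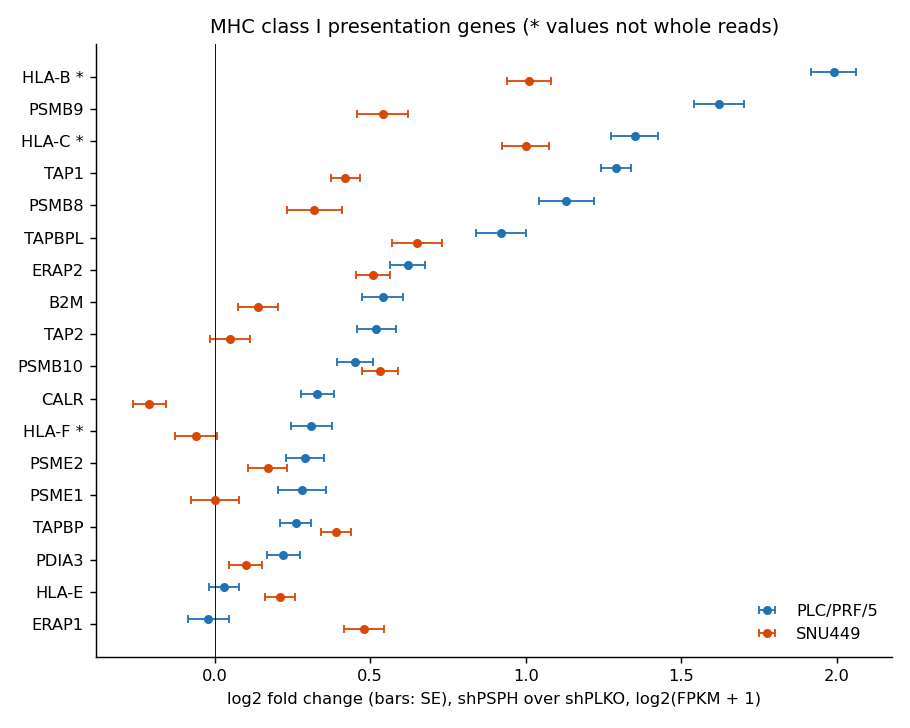
Log2 fold change of FPKM + 1 (horizontal axis, points with SE) of 18 of the 19 tested genes of MHC class I presentation (vertical axis) in PLC/PRF/5 (blue) and SNU449 (orange), with stars at genes whose values are not whole reads. HLA-B rose by 1.99 and 1.01 and TAP1 by 1.29 and 0.42.

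The difference of the effects between the lines was then tested gene by gene. CP fell 6.87-fold in PLC/PRF/5 and rose 1.53-fold in SNU449 (difference -3.21, adjusted p = 2.4e-09), and IGFBP1 had the same adjusted p (difference -4.03). TGM2 differed by -2.97 (adjusted p = 6.2e-09). SORT1, the sorting receptor sortilin, fell from 53.3 ± 0.301 to 16.7 ± 0.0874 FPKM in PLC/PRF/5 and rose from 21 ± 0.0540 to 27.8 ± 0.296 FPKM in SNU449 (-2.0, adjusted p = 2.6e-08). CRH (-2.51, adjusted p = 2.6e-08) was below 1 FPKM in both SNU449 groups. Of all tested genes, 7113 (57.6%) differed in their response, 603 of them by at least 1 on the log2 scale. Of 4611 genes called in PLC/PRF/5 and not in SNU449, 3601 passed this test of the difference, as did 1214 of the 1721 called in SNU449 and not in PLC/PRF/5. These counts include genes near 0 FPKM in one line, where log2(FPKM + 1) leaves no room for a like fall. Of the tested genes, 7384 were at FPKM of at least 5 in all groups. Lists whose effect differed numbered 7, and 5 without the genes with values not whole reads, and 0 were called with an estimated correlation.

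The control libraries were compared to describe the lines themselves. PLC/PRF/5 controls were higher in GSTP1, a glutathione transferase (1189 ± 5.62 FPKM against 0.00824 ± 0.0117), CRH (1104 ± 13.5 against 0.0197 ± 0.0278), APOB, the apolipoprotein of liver lipoproteins (416 ± 0.495 against 0.00112 ± 0.00158), MAGEA4, a cancer-testis antigen (412 ± 14.8, against SNU449 libraries listed at 0), and VTN, vitronectin (405 ± 3.35 against 0.00344 ± 0.00487). SNU449 controls were higher in S100A6, a calcium-binding protein (841 ± 8.82 against 0.0604 ± 0.0339), COL6A3, a collagen chain (441 ± 53.9 against 0.0117 ± 0.0121), SPP1, osteopontin (351 ± 9.32 against 0.412 ± 0.124), SERPINE2, a protease inhibitor (343 ± 12.2 against 0.631 ± 0.0490), and MT1E, a metallothionein (225 ± 20.5 against 0.106 ± 0.0109). Hepatocyte genes were higher in PLC/PRF/5, 27 of 29 (29 differed when adjusted over the list alone) with a median log2 difference of 4.18 (adjusted p = 1.6e-09, and adjusted p = 0.24 with an estimated correlation). Mesenchymal and matrix genes were higher in SNU449, 23 of 31 (29 differed when adjusted over the list alone) with a median of -1.92 for PLC/PRF/5 over SNU449 (adjusted p = 5.2e-05, and adjusted p = 0.36 with an estimated correlation). Genes of the unfolded protein response were higher in PLC/PRF/5, 19 of 20 with a median of 1.23 (adjusted p = 6.1e-05, and adjusted p = 0.24 with an estimated correlation), as were epithelial genes, 11 of 13 with a median of 1.17 (adjusted p = 0.010, and adjusted p = 0.27 with an estimated correlation). Lower there were glycolysis and hypoxia, 20 of 28 with a median of -0.61 (adjusted p = 0.0011, and adjusted p = 0.34 with an estimated correlation), cytosolic ribosomal proteins, 26 of 35 with a median of -0.35 (adjusted p = 0.0052, and adjusted p = 0.78 with an estimated correlation), and G1/S and DNA replication, 24 of 38 with a median of -0.35 (adjusted p = 0.015, and adjusted p = 0.34 with an estimated correlation). In all, 10375 genes (84%) differed, 5579 higher and 4796 lower in PLC/PRF/5.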

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

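The tests of genes expressed in one line alone and of a poor knockdown were chosen only after the results were seen, and the tests of gene length, GC content, expression level and single control libraries before. The values below were singled out because the effect of the knockdown differed between the lines in the test of the difference itself, for 77 of the 87 genes named for the knockdown comparisons and for 7 lists. Genes named only for the control lines were not among these. The rule named genes partly by large, opposite or differing effects in these same data, which favours a high share. Of all tested genes, 57.6% passed the test of the difference. Each value is the log2 fold change in PLC/PRF/5 minus that in SNU449.

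Among genes with at least 1 FPKM in a group of each line, differences of at least 2 towards a lower value in PLC/PRF/5 were IGFBP1 at -4.03, CP at -3.21, TGM2 at -2.97, UBD at -2.26, IGFBP4 at -2.07, C1S at -2.04, KYNU at -2.01 and SORT1 at -2.0. Between 1 and 2 in this direction were MMGT1 at -1.86, ATF5 at -1.62, CCL5 at -1.61, CFB at -1.29, CDK6 at -1.20, ABCC2 at -1.19, GABARAPL1 at -1.17 and NNMT at -1.09. Below 1 in this direction were BHMT2 at -0.95, CLDN1 at -0.86, MKI67 at -0.79, GINS2 at -0.68, ELF3 at -0.65, IGFBP3 at -0.59, IFIT2 at -0.59, RND1 at -0.55, FN1 at -0.55, FOXA1 at -0.53, MCM4 at -0.51, PSPH at -0.44, MCM10 at -0.29, SHMT1 at -0.25, CTSD at -0.24 and AURKA at -0.19.

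Towards a higher value in PLC/PRF/5, differences of at least 2 were EEF1A2 at 2.95, MATN3 at 2.59, CD9 at 2.35, ACHE at 2.26, TTC17 at 2.15 and SLC3A2 at 2.03. Between 1 and 2 were METAP2 at 1.95, LAMB3 at 1.93, SERPINA3 at 1.73, SDHD at 1.69, TMEM9B at 1.49, VIM at 1.48, HSDL2 at 1.30, RPL14 at 1.15, HIST1H2BD at 1.15 and HIST1H2BK at 1.12. Below 1 were HLA-B (values not whole reads) at 0.98, PGK1 at 0.88, SLC25A32 at 0.87, TAP1 at 0.86, FADS1 at 0.66, HMOX1 at 0.65, NUSAP1 at 0.65, CTSL at 0.64, PHGDH at 0.61, PI4K2B at 0.60, ULK1 at 0.53, TRAF1 at 0.52, SCD at 0.42, NDUFA9 at 0.40, KIF20A at 0.38 and PSAT1 at 0.36.

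Other genes were under 1 FPKM in both groups of the other line. SDS at -2.67, CRH at -2.51 and LRP2 at -2.38 fell in PLC/PRF/5, and PSG1 at 2.03, IGFBP2 at 1.57 and PSG5 at 1.34 fell in SNU449, and at such levels log2(FPKM + 1) leaves no room for a like fall in the other line. CCK at 2.30, GAL at 2.27, CTSE at 2.26 and CGB8 at 2.16 rose in PLC/PRF/5 and stayed under 1 FPKM in SNU449. SLFN5 at -1.57 and COL5A1 at -1.04 rose in SNU449 and had means under 1 FPKM in PLC/PRF/5. There SLFN5 was lower after knockdown, whereas COL5A1 was higher, at 0.121 and 0.117 FPKM against 0.0649 and 0.0587 in the control libraries. The size of the COL5A1 difference therefore depends on the 1 added before the logarithm. MMP9 at -0.58 rose in both lines, from 0.206 to 0.963 FPKM in PLC/PRF/5 (4.69-fold) and 2.57-fold in SNU449, so the sign of its difference rests on the 1 added before the logarithm and turns on the scale of FPKM ratios. IFIT2 is near to this, with rises of 2.28-fold and 2.45-fold.

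The lists with a difference, as medians over their members, were acute phase genes at -1.01 (adjusted p = 9.1e-04), NRF2 and glutathione at -0.47 (8.0e-04), G1/S and DNA replication at -0.25 (0.018), replication-dependent histones at 1.09 (0.0021), cytosolic ribosomal proteins at 0.30 (9.1e-04), MHC class I presentation at 0.29 (0.045) and oxidative phosphorylation at 0.19 (0.046). With an estimated correlation the number of lists called was 0. A trend over gene length, GC content and level was tested for the ribosomal protein list in SNU449 alone, and not for the other lists. Without the genes with values not whole reads, MHC class I presentation had an adjusted p of 0.097 and oxidative phosphorylation 0.053.

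Of the 17 genes past 1 on the log2 scale in both lines, 16 went in the same direction, with PSPH, the target of the knockdown, among the 16. Across all tested genes, however, the effects of the knockdown had little in common between the lines, with r = 0.08, and r was 0.16 across genes called in both lines. Genes expressed in one line alone do not account for this, since r was 0.07 across the 7384 genes at FPKM of at least 5 in all groups. A trend over gene length and GC content does not either: fold changes correlated with log2 length at r = -0.17 in PLC/PRF/5 and 0.20 in SNU449, yet r between the lines was 0.11 once a smooth trend over both was taken out (12066 genes). A poor knockdown in either line is argued against by PSPH, of which 11.1% of the control level or less was left. Whether the lines carried different hairpins is not stated, so an effect of the hairpin remains open, as hairpin sequences were not analysed here, and a biological difference between the lines is a further hypothesis that may hold.

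The lower cytosolic ribosomal protein genes in SNU449 (median -0.27) stood against a general trend over gene length, GC content and level. Of 10000 random lists matched on these, 0 had a median as low, but the matched median was -0.14, so such a trend may account for part of the fall. Matching on level was incomplete, with a median of 266 FPKM in matched genes against 555 in the list. Genes of the random lists were drawn independently, so the count of 0 takes no account of list members that vary together. Camera with an estimated correlation gave this list an adjusted p of 0.32 in SNU449. Neither SNU449 control library alone gave the fall, since without either of them the median was -0.26 or lower. The hypothesis of a lower ribosomal protein expression after PSPH knockdown in SNU449 remains open beside these trends and the hairpin.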

How the results depend on the processing

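The alternatives without the genes with values not whole reads and with pseudocounts of 0.1 and 0.5 were chosen after the data were seen, and the others before. A minimum change of 1 on the log2 scale left 443 genes in PLC/PRF/5, 68 in SNU449, 603 differing between lines, 3496 between the control lines and 17 called in both. With an estimated correlation 0 lists were called in PLC/PRF/5 and 1 in SNU449. Leaving out each library in turn, with the lone library of its group assumed to vary like the others, gave 6313 to 8034 genes in PLC/PRF/5, 2831 to 5330 in SNU449, 5907 to 7161 for the difference, 9656 to 10509 between control lines, and 1752 to 3370 called in both. The lowest counts in SNU449 and in both lines came without replicate 1 (2831 and 1766) and without replicate 2 (2848 and 1752) of the SNU449 knockdown, and the cause was not tested. Lists called ranged from 9 to 12 in PLC/PRF/5 and from 16 to 17 in SNU449, and PSPH from -3.27 to -3.01 and from -2.83 to -2.57. Under the other scaling, pseudocounts, filters, fits of a line alone, limma-voom, the replicate block and the fit without genes not on whole reads, these counts, where obtained, stayed within 1.5 times of those reported, and PSPH stayed negative and called. Lists were not tested with limma-voom, and fits of a line alone gave no count for the difference or between control lines. The block gave 7856, 5011, 7236 and 10359 genes in the order above. The minimum change was applied to counts alone. Of the named genes' values under the other alternatives, 3017 kept their call or lack of a call, 31 lost the call, 16 gained it and 0 reversed. For lists these were 809, 35, 6 and 0. Direction was compared only for values called in the main fit or in the alternative, so values called in neither count as kept whatever their sign. With no filter the epithelial and histone lists of SNU449 were no longer called (12 lists in PLC/PRF/5 and 16 in SNU449), whereas the NF-kB and p53 lists of PLC/PRF/5 and the checkpoint list of SNU449 were. With only the 4 SNU449 libraries and with a pseudocount of 0.1, the serine and glycine list of SNU449 was no longer called (16 lists each). The planned tests with DESeq2 and edgeR were not run: the deposited values are FPKM, for which the design named limma-trend, and the recovered reads were used in limma-voom. Genes under the filter's 1 FPKM entered only the fit with no filter, of 18095 genes, which called 7999, 4395, 7263 and 12002 genes in the order above, at a depth of 63332267 reads or more per library.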

Other observations

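The tests of the values not on whole reads were chosen only after the pattern had been seen.

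Markers fixed for other cell types were found at varied levels in these lines. Of 10 endothelial markers, 0 reached a mean of 1 FPKM in any group. Of 14 leukocyte markers, 4 did in PLC/PRF/5 and 2 in SNU449, with the actin-bundling gene LCP1 at 62.3 FPKM in PLC/PRF/5 controls and 0.388 in SNU449 controls, and CD68 at 15.1 and 24.9 FPKM. Of 11 fibroblast or stellate markers, 5 did in SNU449 and 0 in PLC/PRF/5. The collagen gene COL1A2 was at 113 FPKM in SNU449 controls and 188 after knockdown, and COL1A1 at 9.90 and 18.9 FPKM. Of 8 cholangiocyte markers, 5 did in every group, with the keratin gene KRT7 at 3.49 FPKM in PLC/PRF/5 controls and 391 in SNU449 controls.

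In 41 rows, values did not lie on whole reads, among them AKT1, STAT3, JAK1, JAK2, MAPK3, SOCS3, CXCL10, CCL2, HLA-B and HLA-C, named here after their values had been seen. A length or precision outside the search does not account for this in 27 of the 41 rows, which were whole at a common length in at least 5 libraries and off in the others. In these rows 52 of 216 values were off, 5 of 54 in the PLC/PRF/5 control, 27 of 54 in the PLC/PRF/5 knockdown, 11 of 54 in the SNU449 control and 9 of 54 in the SNU449 knockdown. Reads divided between near-identical genes are argued against by other multi-copy families (ribosomal proteins, histones, metallothioneins, tubulins, keratins and aldo-keto reductases), in which 0 of 200 members were off, and the total of another library made at most 1 of the 52 values whole. The cause remains open, no biological explanation was tested, and tests of these genes rest on values whose making is not known.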
